A study of Mus musculus with 9 samples.

How the data were processed

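The series holds one table of gene expression from 9 mouse liver libraries, 3 each from Control, BDL and BDL+BMSC. Its values are estimated counts per gene, deposited by the authors, and 9.03 to 10.3% of the values in a library are not whole numbers. Per the submitters' processing notes, base calls came from CASAVA, the genome was mm9 and differential expression was tested with DESeq2. The aligner, the counting program and all versions are not given in the sources used here. The table holds 55722 entries, of which 55414 are annotated genes and 308 are assembled loci without an annotated name. The assembled loci were left out of library sizes and tests and made up 0.34% of counts in Control, 0.751% in BDL and 0.736% in BDL+BMSC. Of the annotated genes 1709 have no symbol. No coordinates are given, because the table has none and the annotation at hand is of another genome build.

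Estimated counts were rounded to whole numbers. Genes with too few counts were removed by filterByExpr (minimum count 10, minimum total count 15), which left 14738. Libraries were scaled by the trimmed mean of M values (TMM), all 9 were fitted together with the group as the only term, and each comparison was tested with the robust quasi-likelihood F-test of edgeR 4.0.16 in R 4.3.3. P-values were adjusted by the Benjamini-Hochberg method at 0.05. The SE of a log2 fold change was derived from the same test, as its absolute value divided by the square root of the F statistic. It therefore restates the test and is no separate measure of spread. CPM values are scaled by TMM. Gene lists were written before the data were examined, 43 in number, and 41 of them with at least 5 tested genes were tested with camera of limma 3.58.1 on log2 CPM with a prior count of 2 and a preset correlation of 0.01. Camera with an estimated correlation and fry were run beside it. Where a gene had 3 counts or fewer over a whole group, its ratio is given with a 95% counting interval, and at 0 counts as a bound against a floor of 3 counts.

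Genes are named by a rule fixed before the data were examined. It takes the 8 largest rises and the 8 largest falls of each comparison among genes that passed, whose groups do not overlap and that reach 10 CPM in the higher group. It adds 18 fixed genes, up to 4 members with the smallest p of each list described, and the 8 genes called in opposite directions with the smallest p. Some genes that meet the rule are not reported here. The steps were tested on simulated data made from the real means and library sizes, with 200 seeded genes of 14738 changed. The seeded genes were drawn only from genes above a minimum mean CPM in the second group of a comparison. The recovery rates therefore do not apply to genes of low level. At 4-fold the test recovered 96% of the seeded genes in BDL against Control, 96% in BDL+BMSC against BDL and 100% in BDL+BMSC against Control. At 2-fold it recovered 76%, 74% and 88%, at 0.5-fold 72%, 66% and 80%, and at 1.5-fold 12%, 12% and 18%, and 6.57%, 7.46% and 7.74% of its calls were false. Overlaps between comparisons were set against 20 simulated data sets. These drew each gene independently and were fitted without the robust option, so they hold no shift shared by many genes of a library.

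The alternatives tried were DESeq2 1.42.0, limma-voom, median-of-ratios scaling, library size only as scaling, no filter, a stricter filter (CPM of 1 in 3 libraries), a replicate block, a fit of only the 2 groups compared, a 2-fold minimum change and leaving out each library in turn. Including the assembled loci and leaving out 2 libraries together for the matrix genes were added after the data were seen. The comparisons were also repeated over all other splits of the 6 libraries concerned. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.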

Results

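Messenger RNA of mouse liver was sequenced in 9 libraries, 3 from each of 3 groups. The Control group is not described further in the labels. In the BDL group the common bile duct was ligated, an operation that blocks bile outflow and is used as a model of liver fibrosis. In the BDL+BMSC group ligated mice also received BMSCs, transplanted cells whose name the labels do not spell out. The labels conflict on this treatment. The series design names the portal vein and 4 weeks, and the treatment protocol the tail vein and 2 weeks, so route and time are left open here. The libraries held 31217296, 26594863 and 29013962 estimated counts in Control, 25957221, 23774757 and 22951792 in BDL, and 22612292, 25628031 and 25595600 in BDL+BMSC. The labels do not say that the libraries come from separate animals, and p-values then measure only the spread between these samples, which may be technical. Chi-square per degree of freedom, which sets the spread of a pair of libraries against read sampling, was at least 25.45 within Control. It was at least 63.17 within BDL and 61.26 within BDL+BMSC. These values argue against read sampling alone, but other technical steps cannot be told apart from differences between animals.

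Levels are counts normalised to library size (CPM), given as mean ± SD over the 3 libraries of a group, and log2 fold changes are given ± SE. Adjusted p-values of genes come from the quasi-likelihood test of edgeR over 14738 genes in one fit of all 9 libraries, and those of gene lists from camera of limma over 41 lists. Across genes, log2 CPM correlated at r = 0.971 to 0.985 between libraries of a group, at 0.952 to 0.972 between BDL and BDL+BMSC libraries, and at 0.888 to 0.936 between Control and ligated libraries. The first principal component held 63.8% of the variance and placed the Control libraries at -95.1 to -83.5 and the 6 ligated libraries at 24.8 to 58.5. The second held 12.3% and placed BDL libraries at -44.7 to -10.2 and BDL+BMSC libraries at 24.1 to 44.1.

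The comparison of BDL with Control asked which liver transcripts differ after bile duct ligation. Of the lists tested, 23 of 24 bile duct epithelium genes, 17 of 18 monocyte and macrophage genes and 20 of 27 acute phase genes rose, and 23 of 33 fatty acid oxidation genes and 16 of 16 male-biased genes fell. None of these lists was called with an estimated correlation (adjusted p = 0.204 to 0.445). Lcn2, which encodes a secreted acute phase protein that binds bacterial siderophores, rose from 7.76 ± 3.84 CPM in Control to 2628 ± 348 CPM in BDL (log2 fold change 8.40 ± 0.72, adjusted p = 4.84e-05, n = 3 libraries per group). Col1a1 (ENSMUSG00000001506), which encodes a chain of type I collagen, rose from 6.29 ± 3.3 to 80.4 ± 40.1 CPM (3.68 ± 0.52, adjusted p = 0.00104). Fabp1, which encodes the fatty acid binding protein of hepatocytes, fell from 1315 ± 218 to 99.0 ± 54.2 CPM (-3.73 ± 0.35, adjusted p = 4.37e-05).

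Of the 14738 genes tested, 5015 (34%) passed the threshold, 2897 higher and 2118 lower in BDL, and 2731 of them changed at least 2-fold. The largest rises with a clear level included Sult1e1, the estrogen sulfotransferase (log2 fold change 8.44 ± 0.69), the macrophage gene Chil3 (8.27 ± 0.97), Gpnmb, a transmembrane glycoprotein of lipid-laden macrophages (7.16 ± 0.44), and Mmp7, a matrix-degrading protease (6.91 ± 0.44). Slc7a11, the cystine and glutamate exchanger, had 1 count in all Control libraries together and 800 in BDL, a ratio of 809 with a 95% counting interval of 145 to 32000. Timp1, an inhibitor of matrix proteases, had 3 and 972 counts, a ratio of 327 with an interval of 112 to 1590. All 8 of the largest falls were major urinary protein genes, near-identical copies that share reads, so their single values are uncertain. Mup7 fell from 9768 ± 7630 to 0.689 ± 0.394 CPM (-13.80 ± 1.88), and Mup15, Mup19 and Mup1 had log2 fold changes of -13.75 ± 2.27, -13.47 ± 2.5 and -13.03 ± 1.91. Mup13 and Mup-ps3 had no counts in BDL and were at least 1710-fold and at least 617-fold lower against a floor of 3 counts over the group. Mup17 and Mup16, with 1 and 3 counts in BDL, had ratios of 55600 (interval 9980 to 2200000) and 8600 (interval 2940 to 41700).

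Of 24 tested markers of bile duct epithelium, 23 rose, also 23 adjusted over the list alone, with a median log2 fold change of 3.76. The list's adjusted p was 2.16e-14 and adjusted p = 0.204 with an estimated correlation. The keratin genes Krt7 and Krt19 rose by 5.21 ± 0.44 and 4.02 ± 0.34 on the log2 scale. Spp1, which encodes osteopontin, rose from 26.8 ± 4.92 to 669 ± 280 CPM, and the tight junction gene Cldn4 and the collagen receptor gene Ddr1 rose by 6.44 ± 0.48 and 4.34 ± 0.27. Of 6 genes listed as mesothelial markers 4 rose, also 4 adjusted over the list alone (adjusted p = 0.00129, adjusted p = 0.313 with an estimated correlation). They were Krt8, Krt18, Lrrn4 and the mesothelin gene Msln (4.98 ± 0.68). Krt8 and Krt18 are keratin genes not particular to mesothelium, at 223.5 to 293.1 and 159.5 to 213.7 CPM in Control. Lrrn4 and Msln reached at most 2.634 and 4.444 CPM in a BDL library. Among 18 markers of monocytes and macrophages, 17 rose, also 17 adjusted over the list alone, with a median of 4.18 (adjusted p = 6.31e-14, adjusted p = 0.204 with an estimated correlation). They included the chemokine receptor gene Cx3cr1 (5.02 ± 0.34) and Lgals3, which encodes galectin-3 (3.07 ± 0.24), while Adgre1, which encodes the macrophage antigen F4/80, did not pass (0.48 ± 0.24, adjusted p = 0.149). Acute phase genes rose in 20 of 27 cases, also 20 adjusted over the list alone (adjusted p = 3.09e-06, adjusted p = 0.445 with an estimated correlation), among them Cp, which encodes ceruloplasmin (2.08 ± 0.22), and Orm1, which encodes orosomucoid (2.81 ± 0.38). Of 28 cytokine and chemokine genes 20 rose, 21 adjusted over the list alone, including the chemokine gene Ccl6 (3.34 ± 0.22) and Tnfaip3, an inhibitor of NF-kB signalling (3.56 ± 0.27). That list had adjusted p = 8.89e-09, adjusted p = 0.247 with an estimated correlation.

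Of 34 genes of collagens and other matrix proteins, 18 rose and 5 fell in BDL, or 18 and 6 adjusted over the list alone, with a median of 0.99 (adjusted p = 0.00993, adjusted p = 0.568 with an estimated correlation). Beside Col1a1, the type III collagen gene Col3a1 rose by 2.35 ± 0.38, the basement membrane genes Nid1 and Col4a1 by 2.99 ± 0.25 and 1.24 ± 0.15, and Thbs1, which encodes thrombospondin 1, by 4.48 ± 0.26. BDL replicate 3 had a lower level of this list than the other BDL libraries, 0.351 above the Control mean on the log2 scale against 1.03 and 1.12. Of 26 genes of matrix-remodelling enzymes and their inhibitors, 18 rose and 2 fell, or 21 and 3 adjusted over the list alone (adjusted p = 1.77e-06, adjusted p = 0.204 with an estimated correlation). Mmp12 rose by 5.80 ± 0.52 and Mmp9 by 3.38 ± 0.37. Tgfb1, which encodes the cytokine TGF-beta 1, rose by 0.99 ± 0.18 (adjusted p = 0.00157), and Id1, a target of TGF-beta family signalling, rose by 2.97 ± 0.16 (adjusted p = 6.9e-06). Acta2, the smooth muscle actin gene of myofibroblasts, did not pass the test (1.22 ± 0.45, adjusted p = 0.0606). Of 20 stellate cell and myofibroblast markers 8 fell and 2 rose, or 8 and 3 adjusted over the list alone (camera direction down, adjusted p = 0.047, adjusted p = 0.595 with an estimated correlation), and 1 to 4 rose when a library was left out, 1 without Control replicate 1. Among 32 cell cycle genes 21 rose, 24 adjusted over the list alone, with Ccnd1, which encodes cyclin D1, at 3.36 ± 0.42, the proliferation marker Mki67 at 2.12 ± 0.4 and the inhibitor Cdkn1a at 1.79 ± 0.17. The list had adjusted p = 1.77e-06, adjusted p = 0.455 with an estimated correlation. Without Control replicate 1 the count of cell cycle genes that rose was 12, and 12 matrix genes rose and 3 fell. Limma-voom called 13 cell cycle genes higher, and 13 matrix genes higher and 4 lower. Without BDL replicate 2 the count of remodelling genes that rose was 12, and 12 acute phase genes rose without Control replicate 2.

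Genes of cholesterol synthesis rose in 19 of 26 cases, 20 adjusted over the list alone (adjusted p = 5.52e-08, adjusted p = 0.403 with an estimated correlation). Lss rose by 2.27 ± 0.29 and Sqle by 2.21 ± 0.31. In contrast, 23 of 33 genes of fatty acid oxidation fell and 1 rose, 24 and 1 adjusted over the list alone, among them Cpt2, a mitochondrial carnitine palmitoyltransferase gene (-1.30 ± 0.18). The list had adjusted p = 6.88e-10, adjusted p = 0.247 with an estimated correlation. Of 34 genes of drug metabolism 19 fell and 7 rose, 21 and 8 adjusted over the list alone, with Cyp2c29 at -3.11 ± 0.34 and Cyp2a5 at 2.56 ± 0.24 (adjusted p = 0.000582, adjusted p = 0.506 with an estimated correlation). Cyp2e1 fell by 1.54 ± 0.32 (adjusted p = 0.00407). Of 18 bile acid synthesis genes 9 fell and 2 rose, 10 and 2 adjusted over the list alone (adjusted p = 0.00169, adjusted p = 0.455 with an estimated correlation). Cyp7a1, the rate-limiting enzyme of that pathway, did not pass (0.53 ± 0.79, adjusted p = 0.641), nor did Cyp8b1, which sets the share of cholic acid (-4.31 ± 1.73, adjusted p = 0.093). Among bile acid transporters, the uptake carrier gene Slc10a1 fell by 1.34 ± 0.31 (adjusted p = 0.007), the basolateral export gene Abcc4 rose by 2.10 ± 0.18 (adjusted p = 2.73e-05), and the canalicular export gene Abcb11 did not pass (-0.27 ± 0.22, adjusted p = 0.38). Alb, which encodes albumin, did not pass either (-0.65 ± 0.35, adjusted p = 0.18). Genes of other proteins that hepatocytes secrete fell along with these lists in 9 of 26 cases and rose in 1, or 10 and 3 adjusted over the list alone (adjusted p = 0.000356, adjusted p = 0.506 with an estimated correlation). Ttr, which encodes transthyretin, fell by 2.25 ± 0.24 and the apolipoprotein gene Apoa2 by 1.54 ± 0.25.

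All 16 tested male-biased liver genes fell, also 16 adjusted over the list alone, with a median log2 fold change of -3.82 (adjusted p = 2.16e-14, adjusted p = 0.204 with an estimated correlation). Cyp7b1, an oxysterol hydroxylase, fell by 3.62 ± 0.32 and Susd4 fell by 3.72 ± 0.41. Hsd3b5, a hydroxysteroid dehydrogenase of a family of close copies, had 2 counts in BDL and 11750 in Control, a ratio of 5810 with an interval of 1610 to 48000. Of 8 female-biased genes 5 rose, also 5 adjusted over the list alone, with the transcription factor gene Cux2 at 4.93 ± 0.51 and Prom1 at 3.70 ± 0.57 (adjusted p = 0.000343, adjusted p = 0.247 with an estimated correlation). Control replicate 3 stood apart in these lists, with a female-biased level of 1.01 against -0.816 and -0.189 in the other Control libraries and Mup15 at 20.42 CPM against 1476 and 2003 CPM. The summed level of 4 Y-linked genes was 75.8 ± 4.87 CPM in Control, 79.0 ± 19.2 CPM in BDL and 85.2 ± 8.3 CPM in BDL+BMSC. Of 7 erythroid genes 6 fell in BDL, also 6 adjusted over the list alone, with Alas2, the heme synthesis enzyme of red cell precursors, at -4.27 ± 0.42 (adjusted p = 0.000109, adjusted p = 0.313 with an estimated correlation).

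Of the 41 lists, camera with a preset correlation of 0.01 called 33 in BDL against Control, 17 higher and 16 lower, and it called 0 with an estimated correlation, where 7 lists had an unadjusted p under 0.05 and fry called 24. With library size as the only scaling the median of all genes lay at 0.271, and the split was 3991 higher and 1055 lower in place of 2897 and 2118.

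**Figure D1:**
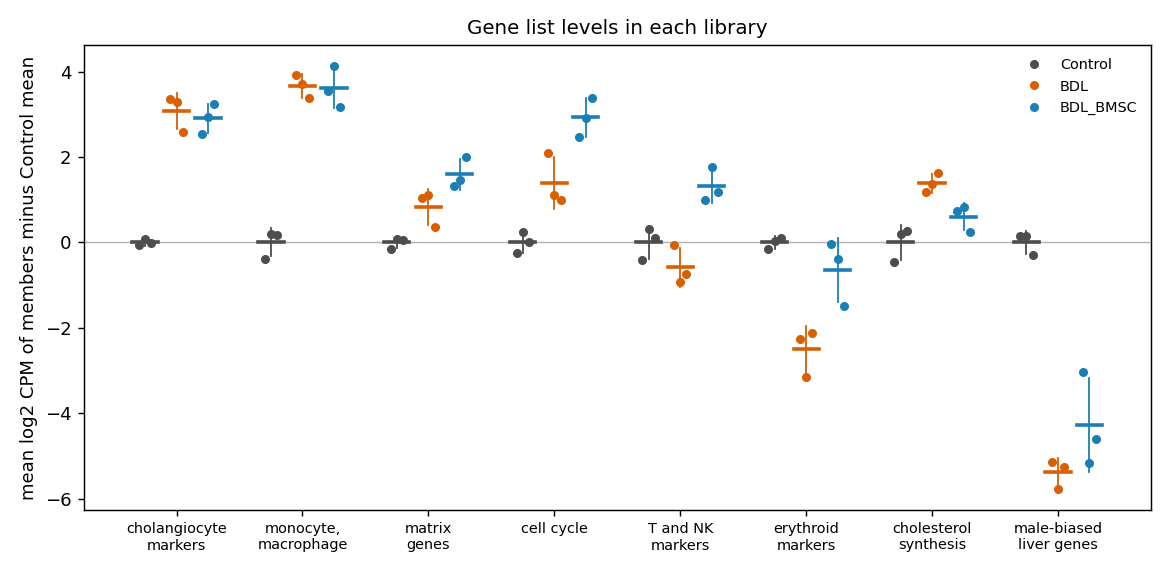
Mean log2 CPM of the tested members of 8 gene lists in each of the 9 libraries, minus the Control mean of the list, on the vertical axis. Points are libraries, thick lines group means and thin lines ± 1 SD (n = 3). Male-biased liver genes lie at -5.38 ± 0.333 in BDL and -4.27 ± 1.1 in BDL+BMSC, and cell cycle genes at 1.40 ± 0.608 and 2.93 ± 0.46.

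The comparison of BDL+BMSC with BDL asked what differs in ligated livers after transplantation. Id1 (ENSMUSG00000042745), a transcriptional inhibitor induced by bone morphogenetic proteins, fell from 55.4 ± 9.33 CPM in BDL to 14.8 ± 0.515 CPM in BDL+BMSC (log2 fold change -1.91 ± 0.15, adjusted p = 0.000991), and Control lay at 7.06 ± 1.11 CPM. Fabp1 rose from 99.0 ± 54.2 to 550.4 ± 14.1 CPM (2.47 ± 0.33, adjusted p = 0.0315), below the Control level of 1315 ± 218. Sult1e1 fell by 3.37 ± 0.44 (adjusted p = 0.0315). Cdc20, an activator of the anaphase-promoting complex, rose to 17.0 ± 6.56 CPM against 1.73 ± 0.865 CPM (3.29 ± 0.44, adjusted p = 0.0315) and Mki67 to 27.0 ± 12.1 CPM against 5.18 ± 1.13 CPM (2.38 ± 0.35, adjusted p = 0.036). Collagen genes had higher means in BDL+BMSC but did not pass, with Col1a1 at 152 ± 45 CPM against 80.4 ± 40.1 CPM (0.92 ± 0.46, adjusted p = 0.342) and Col3a1 at 229.9 ± 65.9 CPM against 102.6 ± 37 CPM (1.16 ± 0.37, adjusted p = 0.149).

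Of the 14738 genes tested, 88 (0.597%) passed the threshold, 54 higher and 34 lower in BDL+BMSC, and 75 of them changed at least 2-fold. The largest rises with a clear level were Clec2h (5.17 ± 0.85), Car3, a carbonic anhydrase of hepatocytes and fat cells (4.11 ± 0.67), the cyclin gene Ccnb2 (3.51 ± 0.5), Cdc20, the kinesin gene Kif20a (3.15 ± 0.51), Cdca3 (2.69 ± 0.44), Fabp1 and Hba-a2, an alpha globin gene that shares reads with its copy (2.42 ± 0.43). The largest falls included Sult1e1, the clock repressor gene Cry1 (-2.43 ± 0.4), Id1, the cytidine deaminase gene Cda (-1.71 ± 0.25), Mmp7 (-1.61 ± 0.29), Tsku (-1.48 ± 0.26) and Nrbp2 (-1.41 ± 0.24). The count of genes changed moved with single libraries. It was 11 without Control replicate 2, 377 without BDL replicate 1, 10 without BDL replicate 2, 2 without BDL replicate 3, 46 without BDL_BMSC replicate 1, 30 without BDL_BMSC replicate 2 and 16 without BDL_BMSC replicate 3. Of the 9 fits that leave out a library, Id1 passed in all 9, Cenpe and Fabp1 in 8, Clec2h and Car3 in 3 and Hba-a2 in 1. DESeq2 called 800 genes, all of the 88 among them, and edgeR called 466 with no filter on low counts, 241 with library size only as scaling (194 higher and 47 lower) and 22 with only the 2 groups compared in the fit.

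Of 32 cell cycle genes 9 rose and 1, Cdkn1a, fell, or 21 and 1 adjusted over the list alone, with a median log2 fold change of 1.59 (adjusted p = 9.38e-15, adjusted p = 0.32 with an estimated correlation). Cenpe, a kinesin of the mitotic spindle, rose by 3.07 ± 0.36 (adjusted p = 0.0209). When a library was left out, 0 to 21 of the 32 rose, and none of them passed without BDL replicate 3. BDL replicate 1 had a higher level of this list than the other BDL libraries, 2.1 above the Control mean on the log2 scale against 1.1 and 1. Markers of T and NK cells rose in 2 of 17 cases, 16 adjusted over the list alone, with a median of 2.00 (adjusted p = 3.23e-14, adjusted p = 0.32 with an estimated correlation). They were Trac, the constant region of the T cell receptor alpha chain, at 1.63 ± 0.808 CPM against 0.158 ± 0.0677 CPM, and Cd5 at 1.07 ± 0.288 CPM against 0.0915 ± 0.0415 CPM. Of 10 B cell and plasma cell markers 1 rose, 9 adjusted over the list alone (adjusted p = 1.92e-06, adjusted p = 0.32 with an estimated correlation). It was Pax5, a B cell transcription factor, with 48 counts against 1 and a ratio of 44.2 with an interval of 7.57 to 1780. Erythroid genes moved with these markers. Hba-a2 was among the 2 of 7 that rose, or 6 adjusted over the list alone (adjusted p = 1.14e-06, adjusted p = 0.32 with an estimated correlation). The level of the list relative to Control was -2.50 ± 0.556 in BDL and -0.64 ± 0.751 in BDL+BMSC. Among 16 genes of antigen presentation 2 rose, 8 adjusted over the list alone, the class II genes Cd74 (1.68 ± 0.26) and H2-Aa (1.78 ± 0.29), with adjusted p = 6.87e-07, adjusted p = 0.409 with an estimated correlation. Of 25 interferon response genes 1 rose, Ifit2 (1.61 ± 0.27), or 15 adjusted over the list alone (adjusted p = 1.51e-10, adjusted p = 0.32 with an estimated correlation). When a library was left out, the number that rose ran from 0 to 8 for T and NK cell markers, 0 to 1 for B cell markers, 0 to 5 for erythroid genes, 0 to 8 for antigen presentation and 0 to 7 for interferon response, with 0 T and NK cell, antigen presentation and interferon genes without Control replicate 2.

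In the matrix list 0 of 34 genes passed edgeR's test over all genes, and 18 were higher and 1 lower adjusted over the list alone. At an unadjusted p under 0.05 there were 21 higher and 1 lower, DESeq2 called 11 higher and limma-voom 0. The median of the list was 0.82 (adjusted p = 1.51e-10, adjusted p = 0.356 with an estimated correlation), and it was 0.57 without BDL replicate 3, the library with the lowest matrix level of the ligated ones. The genes with the smallest p were Col8a1 (1.92 ± 0.41, adjusted p = 0.0613), Postn (1.61 ± 0.37, adjusted p = 0.0702), Thbs2 (1.31 ± 0.32, adjusted p = 0.0812) and Lum (1.14 ± 0.28, adjusted p = 0.0849). Endothelium markers, not only of the sinusoids, were also called higher as a list, with a median of 0.67 (adjusted p = 2.32e-07, adjusted p = 0.459 with an estimated correlation). Of 18, 0 passed edgeR's test and 1 adjusted over the list alone, against 10 higher at an unadjusted p under 0.05, 1 by DESeq2 and 0 by limma-voom. Stellate cell markers had a median of 0.47 (adjusted p = 0.00691, adjusted p = 0.688 with an estimated correlation), and their mean of 0.458 was -0.00301 without BDL_BMSC replicate 3. Of 20, 0 passed edgeR's test and 0 adjusted over the list alone, against 5 higher and 1 lower at an unadjusted p under 0.05, 1 higher by DESeq2 and 0 by limma-voom. Of 26 cholesterol synthesis genes 1 fell, or 16 adjusted over the list alone, with a median of -0.90 (adjusted p = 6.13e-14, adjusted p = 0.32 with an estimated correlation), and 0 to 4 fell when a library was left out. None of 24 bile duct epithelium markers passed edgeR's test, also 0 adjusted over the list alone, against 2 higher and 1 lower at an unadjusted p under 0.05, 1 higher and 1 lower by DESeq2 and 0 by limma-voom, and the list was not called (median -0.25, adjusted p = 0.12). Bone marrow stromal markers were also not called (median 0.19, adjusted p = 0.144): 0 of 12 passed edgeR's test and 0 adjusted over the list alone, against 2 higher at an unadjusted p under 0.05 and 0 by DESeq2 and limma-voom.

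Of the 18 genes fixed before the data were examined, Mki67 rose and Abcc4 fell (-0.89 ± 0.17, adjusted p = 0.0454), and 16 did not pass. When each library was left out in turn, Mki67 passed in 5 of 9 fits and Abcc4 in 1 of 9. Apart from the collagen genes, the log2 fold changes of those that did not pass were 0.59 ± 0.43 for Acta2, -0.90 ± 0.45 for Timp1, 0.20 ± 0.17 for Tgfb1, -0.60 ± 0.32 for Krt7, -0.54 ± 0.28 for Krt19 and 0.06 ± 0.31 for Spp1. They were 1.23 ± 0.8 for Cyp7a1, 1.19 ± 1.57 for Cyp8b1, -0.30 ± 0.3 for Slc10a1, 0.10 ± 0.22 for Abcb11, -0.16 ± 0.32 for Cyp2e1, 0.35 ± 0.35 for Alb, -0.91 ± 0.52 for Lcn2 and 0.67 ± 0.24 for Adgre1. Their adjusted p-values lay between 0.149, which belonged to Col3a1, and 0.94, which belonged to Spp1. Camera called 19 of 41 lists, 10 higher and 9 lower, and 0 with an estimated correlation, where 2 had an unadjusted p under 0.05. Fry called 2, the T and NK cell and the B cell markers.

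**Figure D2:**
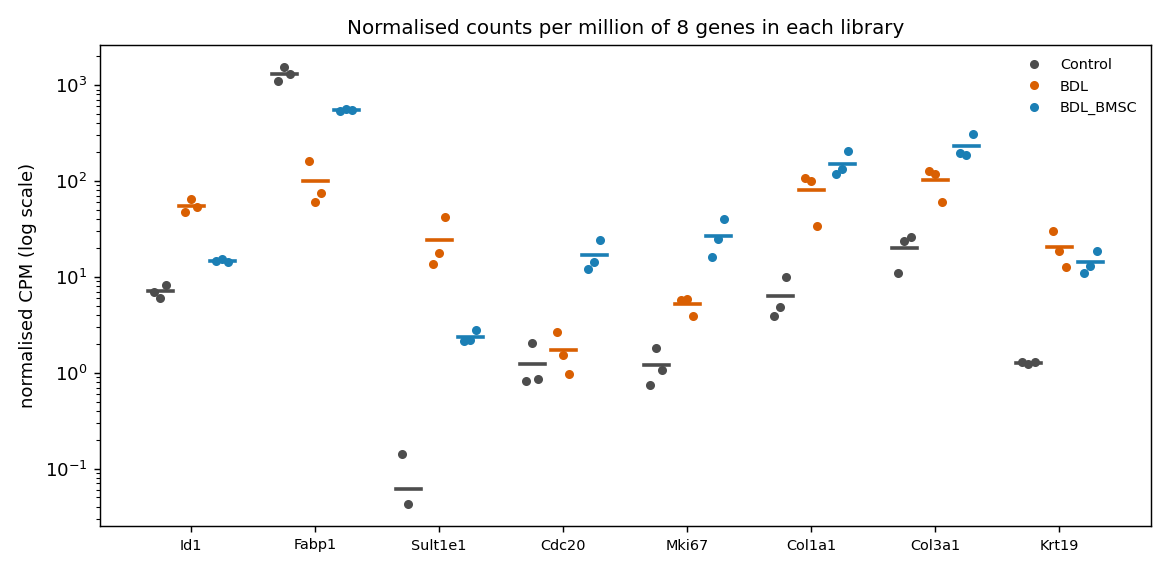
Normalised level (CPM) of 8 genes in each of the 9 libraries, on a logarithmic vertical axis. Points are libraries and lines group means (n = 3), and the Control library of Sult1e1 at 0 is not drawn. Id1 lies at 14.3 to 15.3 CPM in BDL+BMSC and at 47.2 to 65.5 CPM in BDL. Col1a1 of BDL+BMSC at 119.1 to 203.5 CPM overlaps none of the BDL libraries at 34.3 to 107.1 CPM, but did not pass the test. Of all genes tested, 21.7% did not overlap between these 2 groups, and 10% would not by chance.

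The comparison of BDL+BMSC with Control gave the level of each gene in transplanted ligated livers relative to Control. Of the lists tested, 30 of 32 cell cycle genes, 23 of 34 matrix genes and 18 of 18 macrophage genes rose, and 16 of 16 male-biased genes, 22 of 33 fatty acid oxidation genes and 19 of 29 amino acid metabolism genes fell. None of these lists was called with an estimated correlation (adjusted p = 0.314 to 0.436). Col1a1 rose from 6.29 ± 3.3 to 152 ± 45 CPM (log2 fold change 4.60 ± 0.54, adjusted p = 0.000365), Acta2 rose by 1.81 ± 0.45 (adjusted p = 0.0109) and Mki67 by 4.50 ± 0.41 (adjusted p = 5.19e-05). Of 14738 genes, 5798 (39.3%) passed, 3297 higher and 2501 lower, and 3052 changed at least 2-fold. The largest rises included Gpnmb (7.78 ± 0.44), Lcn2 (7.50 ± 0.69), the aldose reductase family gene Akr1b7 (6.73 ± 1.42), Chil3 (6.32 ± 0.95), Ly6d (6.08 ± 0.44) and the glutathione transferase genes Gsta5 (7.97 ± 0.62) and Gsta1 (6.22 ± 1.05), which share reads with close copies. Sprr1a, which encodes a small proline-rich protein of stressed epithelium, had 978 counts against 1, a ratio of 911 with an interval of 163 to 36000. Of the 8 largest falls 6 were major urinary protein genes, with Mup7 at -9.77 ± 1.61, and the others were Hsd3b5 (-9.78 ± 0.54) and the pseudogene Serpina4-ps1 (-8.63 ± 0.52), all of families whose copies share reads. With library size as the only scaling the median of all genes lay at 0.334 and the split was 4844 higher and 832 lower.

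Of 32 cell cycle genes 30 rose, also 30 adjusted over the list alone, with a median of 3.35 (adjusted p = 7.51e-14, adjusted p = 0.314 with an estimated correlation), and Cenpe rose by 5.59 ± 0.45. All 18 monocyte and macrophage markers rose, also 18 adjusted over the list alone (adjusted p = 1.7e-13, adjusted p = 0.314 with an estimated correlation), including Trem2, a lipid receptor of macrophages (4.04 ± 0.35). Of the 34 matrix genes 23 rose and 3 fell, 24 and 3 adjusted over the list alone, with a median of 1.70 (adjusted p = 5.22e-07, adjusted p = 0.436 with an estimated correlation). Without Control replicate 2 only 1 of them fell. Col3a1 rose by 3.51 ± 0.4, Nid1 by 3.06 ± 0.25 and Thbs1 by 3.78 ± 0.26. T and NK cell markers rose in 9 of 17 cases, 11 adjusted over the list alone (adjusted p = 0.00218, adjusted p = 0.436 with an estimated correlation). Among them were Gzmb, which encodes the cytotoxic protease granzyme B (2.83 ± 0.51), and Cd8a (2.17 ± 0.51), while the erythroid level of the same libraries was -0.64 ± 0.751 relative to Control. Without BDL_BMSC replicate 2 the number of T and NK cell markers that rose was 5. All 16 male-biased genes fell, also 16 adjusted over the list alone, with a median of -3.03 (adjusted p = 3.54e-11, adjusted p = 0.314 with an estimated correlation). Of 29 genes of glucose synthesis, the urea cycle and amino acid metabolism 19 fell, 21 adjusted over the list alone (adjusted p = 5.22e-07, adjusted p = 0.436 with an estimated correlation), and 8 fell without Control replicate 1. Hal, the histidine ammonia lyase, lay at -1.90 ± 0.38 and Tdo2, the tryptophan dioxygenase, at -1.60 ± 0.34. Of 33 fatty acid oxidation genes 22 fell and 1 rose, also 22 and 1 adjusted over the list alone (adjusted p = 8.61e-08, adjusted p = 0.315 with an estimated correlation), with Cpt2 at -1.52 ± 0.18. Secreted hepatocyte proteins fell with them in 13 of 26 cases and rose in 1, or 15 and 1 adjusted over the list alone (adjusted p = 8.63e-05, adjusted p = 0.436 with an estimated correlation), and 8 fell without BDL_BMSC replicate 2. So did 8 of 15 mitochondrially encoded genes, also 8 adjusted over the list alone (adjusted p = 0.000826, adjusted p = 0.436 with an estimated correlation), with mt-Co2 at -1.29 ± 0.24, and 3 fell without Control replicate 1. Camera called 31 lists, 20 higher and 11 lower, and 0 with an estimated correlation, where 5 had an unadjusted p under 0.05, and fry called 30.

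The ligation pattern was then followed into the transplanted group. Of the 5015 genes changed in BDL against Control, 78.25% were also changed in the same direction in BDL+BMSC against Control, 2392 of the 2897 that rose and 1532 of the 2118 that fell. The genes that rose had a median log2 fold change of 1.38 in BDL and 1.45 in BDL+BMSC, and those that fell -0.80 and -0.69. Because both comparisons use the same Control libraries, 20 simulated data sets in which BDL+BMSC equalled BDL were made, and they gave a mean share of 82.71% (81.87 to 83.46%), while simulations without any effect gave 0% and independent lists would give 20.09%. The fold changes of both comparisons had a covariance of 1.405 over genes, against 0.0648 in simulations without effect, a difference of 1.34. Simulations in which BDL+BMSC equalled BDL gave 1.784 (1.739 to 1.851), a difference of -0.3792. The Control libraries are too few to be split, and part of the excess over independent lists may come from sharing them.

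Genes changed in opposite directions by ligation and in BDL+BMSC against BDL numbered 42, of which 22 rose after ligation and fell in BDL+BMSC and 20 did the reverse, and 7 changed in the same direction in both. Those with the smallest p-values included Id1, Fabp1, Gm43738, Sult1e1, Dynll1, Pax5 and Rnd2. Dynll1, a dynein light chain gene, rose by 2.27 ± 0.19 after ligation and fell by 1.16 ± 0.18 in BDL+BMSC. Rnd2, which encodes a small GTPase, rose by 2.26 ± 0.21 and fell by 1.24 ± 0.2, and the predicted gene Gm43738 rose by 1.53 ± 0.19 and fell by 1.41 ± 0.19. Both comparisons use the BDL libraries, which alone gives opposite signs, and 20 simulations in which BDL+BMSC equalled BDL gave a mean of 0.15 and at most 1 such gene, while independent lists would give 14.44. Because the simulations hold no shifts shared by many genes of a library, they cannot say how many opposite calls such shifts would give. The covariance of the fold changes was -0.2405, against -0.0703 in simulations in which BDL+BMSC equalled BDL and -0.066 in simulations without effect. The differences were -0.1702 and -0.1745, and part of the excess may come from the shared BDL libraries, which are too few to be split. Their correlation was -0.3097, stronger than -0.1394 in the former simulations but weaker than -0.5062 in the latter. The count of genes called in opposite directions was 5 without Control replicate 2, 149 without BDL replicate 1, 9 without BDL replicate 2 and 2 without BDL replicate 3. It was 14 without BDL_BMSC replicate 1, 21 without BDL_BMSC replicate 2 and 12 without BDL_BMSC replicate 3, and DESeq2 gave 327.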

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

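The tests of blood, of BDL replicate 3 with its criterion, of females, of near-identical copies and of fewer hepatocytes were chosen only after the result was seen, while those of other splits, of lymph node pieces and of scaling were written before. The share of counts on assembled loci, which the comparisons leave out, was higher in ligated livers than in Control. It was 0.751% (SD 0.072) in BDL and 0.736% (SD 0.1) in BDL+BMSC, against 0.34% (SD 0.014) in Control, with n = 3 libraries each. Of 218 such loci tested, 97 changed in BDL against Control (64 higher and 33 lower), 91 in BDL+BMSC against Control (58 higher and 33 lower) and 1, lower, in BDL+BMSC against BDL. One locus alone took 3.95 to 34.8% of these counts in a library. No technical explanation was tested for this share.

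In BDL+BMSC 2 of 17 T and NK cell genes were higher than in BDL and 9 of 17 higher than in Control, and the list was not called with an estimated correlation (adjusted p = 0.32 and 0.436). Blood left in the tissue would raise erythroid genes along with them, and against BDL it stays open, since the T and NK level minus the erythroid level was 1.92 ± 0.484 in BDL and 1.95 ± 0.828 in BDL+BMSC, only 0.0302 apart. Against Control blood cannot be told apart either: the lowest BDL+BMSC value was 1.04 and the highest Control value 0.273, but ligation alone moved this measure as far in BDL. Pieces of lymph node cannot be told apart, since only 4 of 11 such genes could be tested (median log2 fold change 1.37), and the counts of the 10 found summed to 161 in BDL and 507 in BDL+BMSC. All 17 tested members of the list had a positive log2 fold change against BDL. Trdc, the constant region of the T cell receptor delta chain and not a member of the list, went the other way. It lay at 3.919 CPM in BDL and 0.147 CPM in BDL+BMSC (-4.606 ± 0.863, adjusted p = 0.049), and passed in 1 of the 9 fits that leave out a library. A larger number of lymphocytes in the tissue after transplantation remains possible.

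Matrix genes were called higher in BDL+BMSC than in BDL as a list, but not with an estimated correlation (adjusted p = 0.356), and edgeR called 0 of the 34 genes, DESeq2 11 and limma-voom 0. Without BDL replicate 3 the median was 0.574 in place of 0.818, with 30 of 34 genes above 0, and a weaker response of that library alone cannot be told apart from a group effect, since the list levels of the other BDL libraries (1.03 and 1.12) lie close below the lowest of BDL+BMSC (1.32). The criterion was changed from camera (adjusted p = 3.89e-07 without that library) to fry after the other splits were seen, and fry decides nothing here, as it did not call the list with all libraries either (adjusted p = 0.0963, and 0.239 without that library). With library size only as scaling the median was 0.876. That scaling also moved the median of all genes up, to 0.0884, so it could not have lowered the list, and the test does not exclude scaling. With both scalings the list lay above the median of all genes, which was 0.00124 with TMM. The real median difference of 0.793 was matched by 1 of 10 splits of the ligated libraries, the real one, and the highest other was 0.713, so the splits are too few to decide.

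After ligation 16 of 16 male-biased liver genes were lower and 5 of 8 female-biased genes higher, and neither list was called with an estimated correlation (adjusted p = 0.204 and 0.247). Females among the ligated mice are excluded, since the lowest summed level of 4 Y-linked genes in a ligated library was 57.33 CPM. Reads shared between near-identical copies are excluded as the whole cause, since 6 of 6 male-biased genes outside such families were lower. Fewer hepatocytes are excluded as the whole cause, since the median of male-biased genes lay -3.36 from that of hepatocyte secretory genes (-3.82 against -0.465, permutation p over genes = 1e-05 with 100000 resamples, the smallest possible). A loss of the male pattern of liver expression with bile duct ligation remains as the biological explanation, and it was not tested further.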

How the results depend on the processing

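Including the assembled loci and leaving out 2 libraries together for the matrix genes were chosen only after the result was seen, and the other alternatives were fixed before the data were examined. For genes changed in BDL_BMSC vs BDL the count of 88 was 800 with DESeq2, 241 with library size only, 466 with no filter and 22 with only the 2 groups compared, and it ran from 2 to 377 when a library was left out. For genes called in opposite directions in BDL vs Control and BDL_BMSC vs BDL the count of 42 was 327 with DESeq2, 100 with library size only, 177 with no filter and 9 with only the 2 groups compared, and it ran from 2 to 149 when a library was left out. The cause was not tested. A 2-fold minimum change left 2731 genes in BDL vs Control and 3052 in BDL_BMSC vs Control, by construction. With a replicate block the counts were 35 of genes changed in BDL_BMSC vs BDL and 18 of genes called in opposite directions, and 4419 and 5235 in BDL vs Control and BDL_BMSC vs Control. The labels do not say that the numbers pair the libraries. Same-numbered ones correlated at -0.195 to 0.244 and 2 of 9 correlated best with their own number, which shows no pairing but cannot exclude one with 3 libraries per group. Gene lists called in BDL vs Control, BDL_BMSC vs BDL and BDL_BMSC vs Control numbered 0, 0 and 0 by camera with estimated correlation, and fry called 2 in BDL_BMSC vs BDL. The mean log2 fold change of autophagy_lysosome turned to 0.0391 in BDL vs Control and 0.116 in BDL_BMSC vs Control with library size only, and that of oxidative_phosphorylation to 0.0803 in BDL vs Control, where the median of all genes itself lay at 0.271 and 0.334. The mean of stellate_myofibroblast_markers in BDL_BMSC vs BDL ran from -0.00301 without BDL_BMSC replicate 3 to 0.643 without BDL_BMSC replicate 1. When a library was left out, the log2 fold change of these genes that had not passed changed sign: Cyp7a1 in BDL vs Control (-0.4363 to 1.385), and in BDL_BMSC vs BDL Abcb11 (-0.09245 to 0.3056), Cyp2e1 (-0.394 to 0.1456), Cyp8b1 (-1.224 to 4.758) and Spp1 (-0.2498 to 0.2663). The median of the matrix list in BDL_BMSC vs BDL was 0.293 without BDL replicate 3 and BDL_BMSC replicate 3 together. No gene called in BDL vs Control or BDL_BMSC vs BDL changed sign in the fits fixed before the data were examined, and 42 of 5798 in BDL_BMSC vs Control did with library size only.

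Splits of the 6 libraries of a comparison are too few for a share under 0.05. The real grouping alone gave 5015, 88 and 5798 changed genes, 1 of 10 splits in each comparison, and the highest other count was 0. Every other split mixes the groups and so puts their difference into the spread within groups. A low count there follows from the method, above all in the comparisons with Control, and decides nothing. For gene lists, 1 of 10 splits reached 33 in BDL vs Control (highest other 28) and 1 of 10 reached 31 in BDL_BMSC vs Control (highest other 29), but 7 of 10 reached 19 in BDL_BMSC vs BDL (highest other 26). For the opposite calls 2 of 20 assignments of the ligated libraries reached 42. They were the real one and the same split with the names of BDL and BDL+BMSC swapped, which gave 50. The other 18 gave 0, but these splits also called 0 genes in BDL+BMSC against BDL. An opposite call was therefore impossible in them, and their 0 adds nothing. For the share of 78.25% it was 13 of 20 (highest other 91.38).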

Other observations

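No test in this part was chosen after the result was seen. Several groups of genes that the report leaves out also differed after ligation. Neutrophil markers rose in BDL against Control in 8 of 12 cases, also 8 adjusted over the list alone, with a median log2 fold change of 2.82 (adjusted p = 7.41e-05, adjusted p = 0.247 with an estimated correlation), among them the growth factor receptor gene Csf3r (2.64 ± 0.28) and the chemokine receptor gene Cxcr2 (3.47 ± 0.48). Genes of the NRF2 and glutathione response rose in 18 of 29 cases and fell in 2, also 18 and 2 adjusted over the list alone (adjusted p = 7.61e-05, adjusted p = 0.204 with an estimated correlation), with the quinone reductase gene Nqo1 at 2.14 ± 0.21 and the heme oxygenase gene Hmox1 at 1.88 ± 0.18. Immediate early and heat shock genes, a list kept as a measure of RNA quality, rose in 10 of 18 cases, also 10 adjusted over the list alone (adjusted p = 0.000134, adjusted p = 0.204 with an estimated correlation). They included the transcription factor genes Atf3 at 3.17 ± 0.26 and Klf6 at 2.39 ± 0.22. The heat shock genes Hspb1 and Dnajb1 lay at 12.97 to 17.49 and 28.05 to 37.26 CPM in Control, and at 13.83 to 18.7 and 26.14 to 31.22 CPM in BDL. Hspa8, also a heat shock gene, was higher without overlap, at 1035 to 1257 CPM in Control and 1313 to 1580 CPM in BDL. Mitochondrially encoded genes, also an RNA quality list, fell in 3 of 15 cases, 1 adjusted over the list alone (adjusted p = 0.0197, adjusted p = 0.511 with an estimated correlation). Markers of endothelium, not only of the sinusoids, fell in 8 of 18 cases and rose in 1, or 10 and 1 adjusted over the list alone (adjusted p = 0.000302, adjusted p = 0.506 with an estimated correlation). Among those that fell were Plvap (-1.12 ± 0.22) and the VEGF receptor gene Kdr (-1.65 ± 0.39). Without Control replicate 1 the number that fell was 5.

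In BDL+BMSC against BDL, genes of the unfolded protein response had a median of -0.65 (adjusted p = 6.37e-07, adjusted p = 0.356 with an estimated correlation). None of 23 passed edgeR's test, against 7 lower adjusted over the list alone, 11 lower at an unadjusted p under 0.05, 7 lower by DESeq2 and 0 by limma-voom. Immediate early and heat shock genes, a list kept as a measure of RNA quality, were lower too, with a median of -0.30 (adjusted p = 0.00203, adjusted p = 0.32 with an estimated correlation). None of 18 passed edgeR's test, against 2 lower adjusted over the list alone, 5 lower at an unadjusted p under 0.05, 3 lower by DESeq2 and 0 by limma-voom. The members with the smallest p here were the heat shock genes Hsph1, Hspb1, Hspa8 and Dnajb1. Immediate early genes of the list differed among themselves. Egr1 lay at 46.08 to 59.75 CPM in BDL and 52.32 to 59.21 CPM in BDL+BMSC, which overlap. Fos was lower without overlap, at 7.078 to 8.019 CPM in BDL and 5.518 to 6.447 CPM in BDL+BMSC. Acute phase genes had a median of -0.53 (adjusted p = 5.4e-06, adjusted p = 0.527 with an estimated correlation). None of 27 passed edgeR's test, against 1 lower adjusted over the list alone, 6 lower at an unadjusted p under 0.05, 2 by DESeq2 and 0 by limma-voom. BDL_BMSC replicate 3 stood apart in this list, 0.639 above the Control mean on the log2 scale. The other BDL+BMSC libraries lay at 2.23 and 1.86, and the BDL libraries at 2.2 to 2.43.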
